A study of Arabidopsis thaliana with 24 samples.

How the data were processed

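Whole seedlings of wt, fc2, flu and fc1 at 0, 30 and 120 min of light were profiled on 24 Affymetrix arrays, 2 biological replicates per genotype and time, per the labels. Biotin-labelled cRNA was hybridised, per the labels' protocols. The deposited values are log2 signals made by the authors with RMA, per the submitters' processing notes, which background-corrects, normalizes and summarises the probes. The version of RMA and the software that ran it are not given in the sources used here. No further normalization was applied, and the signals were not re-derived from raw images.

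All 22217 probe sets of the table were tested. The platform table and the gene table of the TAIR10.1 annotation, used for names only, gave 1 gene to 13171 probe sets and several genes to 482, and 8564 had no listed gene. The 13171 probe sets named 13029 genes, of which 123 had over 1 probe set. The AFFX control probe sets were to be left out, and the table held 0 of them. Symbols are those of the tables, or else locus identifiers.

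A linear model with 1 mean per group was fitted over all 24 arrays with limma 3.58.1 (R 4.3.3) and empirical Bayes moderation. The tests were two-sided, with Benjamini-Hochberg adjustment within each of 25 contrasts, and called means an adjusted p under 0.05. The contrasts were the light response of each genotype at 30 and 120 min, each mutant against wt at each time, the differences between the light responses of each mutant and wt (the interactions), and fc2 against flu at 30 and 120 min. Groups of 2 arrays are too small for a test of outlying arrays or of other splits of the samples, and neither was made. Tables and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

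Genes named or ranked had probe sets with exactly 1 gene. They were the 5 largest rises and the 5 largest falls of each contrast among called probe sets whose 2 arrays lay outside the range of the other group (for interactions, called probe sets), and up to 4 members of each described list with the smallest p. FC1, FC2 and FLU were to be named throughout, but no probe set named them alone. A gene may be followed across contrasts. Other probe sets may have changed more.

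Design, contrasts, tests, the rule for named genes and 22 gene lists were fixed before the data were examined. Of these lists 9 had at least 3 measured members and were tested with the camera test of limma at a preset correlation of 0.01, adjusted over the lists of a contrast. They were light harvesting (3 of 20 members measured), photosystem and Calvin cycle (7 of 31), tetrapyrrole synthesis (10 of 32), flavonoid synthesis (4 of 18), singlet oxygen (3 of 16), calcium and touch (5 of 8), auxin and elongation (4 of 21), autophagy and senescence (9 of 19) and root (3 of 13). The remaining 13 were too small, and their measured members are reported singly: carotenoid synthesis (1), light signalling (2), oxidative stress (1), jasmonate (0), salicylate and defence (2), ethylene (1), abscisic acid (1), heat shock (2), circadian clock (1), iron (2), plastid proteases (1), seed reserves (1) and reference genes (2). A further 3 lists defined by rule, plastid-encoded, mitochondrion-encoded and ribosomal protein genes, had 0 measured members. After the annotation was seen and before any group difference was computed, 15 lists were added from the named genes and adjusted separately: wall loosening, detoxification, early immunity, further jasmonate, thylakoid assembly, organelle RNA, redox, further protein folding, cold and dehydration, further auxin, cell division, sugar transport, further clock, further seed and reproductive genes.

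The alternatives planned were scaling to the reference genes AT4G34270 and AT2G28390, leaving out the dimmest 40% of probe sets, moderation with a trend and robust variances, the replicate number as a block, leaving out each array in turn, an estimated correlation within lists, the mean of all probe sets per gene, and a change of at least 2-fold for the overlap. Chosen after seeing the data were the mean of the seed-maturation genes M10, M17, PAP85 and OLEO3 as a covariate, leaving out the seed-richer array of 6 groups, equal spread on all arrays, and the spread of each array as a covariate.

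The fit was tested on 22217 simulated probe sets for fc2 against wt at 120 min. It recovered 98% of log2 changes of 1 and 100% of those of 2, with 7 false calls. Camera called a shifted but not an unshifted list. This sets no error rate for real lists or noisier groups.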

Results

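Gene expression was measured in whole 4-day-old Arabidopsis seedlings of the Col-0 accession grown for 4 days without light and moved to white light (120 µmol m-2 s-1, 22 °C) for 0, 30 or 120 min. This first exposure to light starts de-etiolation, the change from a pale, elongating seedling to a green one. The 4 genotypes were the wild type (wt), the ferrochelatase mutants fc2-1 (fc2 below) and fc1-1 (fc1), and flu, a mutant of a negative regulator of tetrapyrrole synthesis. Ferrochelatases make haem from protoporphyrin IX, and dark-grown flu seedlings are known to accumulate protochlorophyllide, which produces singlet oxygen in the light. Each genotype and time had 2 arrays that the labels call biological replicates, so 24 Affymetrix arrays fell into 12 groups, and 22217 probe sets were tested. The labels say no more about the origin of the replicates, so p-values measure only the spread between these arrays, and the number of arrays limits the precision of every value.

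The medians of the deposited log2 values lay between 5.98 and 6.23 on the 24 arrays. The correlation between the replicates of a group, across probe sets, was 0.9907 to 0.9986, and the lowest correlation between any 2 arrays was 0.9177. Changes are log2 differences of group means ± SE from limma (n = 2 arrays per group), with adjusted p-values over all probe sets. The SE pools the spread of all 12 groups, so it may be too small for noisier ones such as wt at 120 min. List means are given ± SD over the members. FC1, FC2 and FLU had no probe set named for them alone, so their levels were not analysed or used to check the genotype labels.

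**Figure D1:**
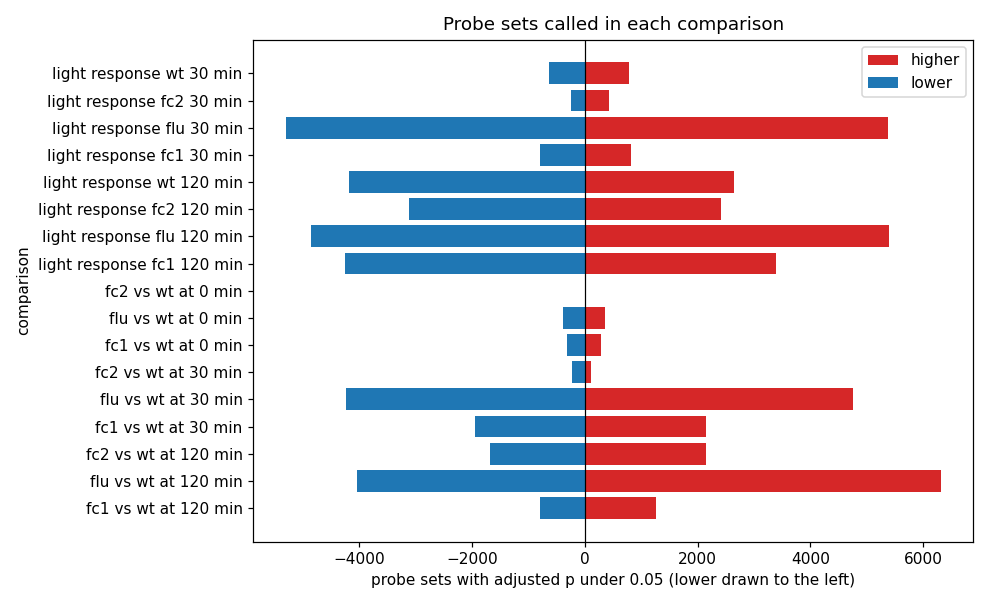
Number of called probe sets (horizontal axis) in 17 comparisons of groups, with bars for probe sets called higher drawn to the right of 0 and bars for those called lower drawn to the left. The count at 120 min ranged from 2055 in fc1 against wt to 10354 in flu against wt.

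Transcripts of seed maturation varied between arrays, within groups and between genotypes. The mean log2 level of M10, M17, PAP85 and OLEO3, genes of seed maturation and storage, ranged from 5.28 to 9.62 over the 24 arrays. Replicates of one group could differ, as in fc1 at 30 min (8.83 and 5.57), fc2 at 30 min (7.95 and 5.58) and wt at 120 min (5.5 and 7.88). Both dark arrays of fc2 (5.84 and 5.84) lay below both of wt (8.14 and 7.36), and both arrays of flu at 30 min (9.28 and 9.02) lay above both of wt (8.54 and 8.79). All 4 arrays of flu at 0 and 30 min lay above the 4 of fc2.

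**Figure D2:**
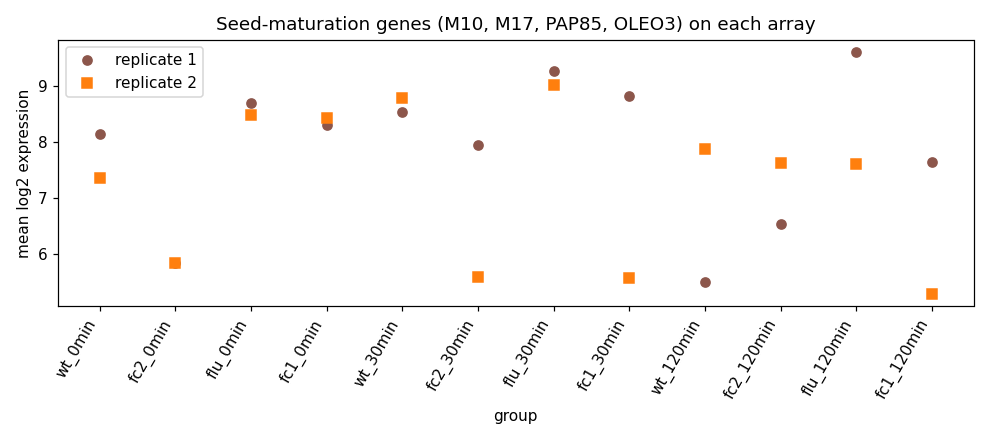
Mean log2 expression of the seed-maturation genes M10, M17, PAP85 and OLEO3 (vertical axis) on each of the 24 arrays, 1 point per array, by genotype and minutes of light. The values run from 5.28 to 9.62 and differ between replicates of several groups, and the replicates of fc2 at 0 min (5.84 and 5.84) lie on top of each other.

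After 30 min, STZ (AT1G27730), a zinc-finger transcription factor of stress responses also called ZAT10, rose by 3.55 ± 0.21 (n = 2 arrays per group, adjusted p = 2.1e-09). AT5G48570, an immunophilin of the FKBP type (3.2 ± 0.39), the small heat-shock protein gene AT1G54050 (3.15 ± 0.24), AT1G73480 (3.03 ± 0.17) and AT5G39670 (2.96 ± 0.26) rose by similar amounts. IAA29 (AT4G32280), an auxin-response repressor of the Aux/IAA family, showed the largest fall (-3.12 ± 0.16, adjusted p = 6.53e-10). It was followed by AT3G53250 (-2.49 ± 0.2), AT5G62280 (-2.2 ± 0.33), the brassinosteroid-responsive gene EXO (-2.05 ± 0.1) and P1R3 (-1.96 ± 0.15).

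Among the gene lists in wt at 30 min, 3 of 5 measured calcium and touch genes rose (3 adjusted over the list alone). CML37 rose by 1.79 ± 0.19 and AT3G01830, the calmodulin-like CML40, by 1.66 ± 0.25, and the list mean was 0.81 ± 0.93 (adjusted p = 0.00222). With an estimated correlation the list was not called (adjusted p = 0.0536 with an estimated correlation). Of 4 flavonoid genes, 2 rose (2 adjusted over the list alone), UGT78D2 by 1.69 ± 0.13 and CHIL by 0.6 ± 0.12, and the list shifted up by 0.58 ± 0.79 (adjusted p = 0.0028). Of 4 auxin and elongation genes, 2 fell (2 adjusted over the list alone), IAA29 and the expansin EXPA8 (-0.43 ± 0.12), with a list mean of -0.94 ± 1.46 (adjusted p = 0.00256). Of 3 singlet-oxygen genes, STZ alone rose (1 adjusted over the list alone), while AT5G64870 had a value of 0.08 ± 0.14 and AT3G28580 of 0.01 ± 0.1 (list adjusted p = 0.00843, and adjusted p = 0.0536 with an estimated correlation). None of 9 autophagy genes passed the test (0 adjusted over the list alone), and their mean of -0.17 ± 0.09 was called as a list (adjusted p = 0.0305, adjusted p = 0.328 with an estimated correlation, and adjusted p = 0.0541 with the seed-maturation covariate). No photosystem, Calvin cycle or tetrapyrrole gene passed the test, and of the light-harvesting genes LHCB4.3 rose (0.75 ± 0.11).

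The clock gene GI rose by 1.43 ± 0.11 in wt at 30 min, where the seed-maturation mean was 8.54 and 8.79, against 8.14 and 7.36 in the dark. In all, 1425 probe sets were called in wt at 30 min, 793 higher and 632 lower, and 374 of them changed at least 2-fold. With scaling to the reference genes, which lowered the median of all probe sets from -0.02 to -0.1, the share of higher calls went from 55.6% to 36.2%. Without replicate 1 of dark wt the count was 837, and without its replicate 2 it was 887.

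After 120 min in wt, AT1G60590 (5.9 ± 0.17), AT5G42760 (5.8 ± 0.14, adjusted p = 1.98e-14) and AT1G48100 (5.6 ± 0.16) had risen most, followed by AT3G56290 (4.42 ± 0.21) and MSRB6, a methionine sulfoxide reductase (4.24 ± 0.19). The largest falls were in AT5G57760 (-4.83 ± 0.14), AT5G02540 (-4.23 ± 0.25), AT2G34020 (-3.56 ± 0.12), AT5G02580 (-3.37 ± 0.13) and AT4G11610 (-3.34 ± 0.16). All 4 flavonoid genes rose (4 adjusted over the list alone), with a mean of 2.17 ± 1.06 (adjusted p = 1.88e-05). The largest were UGT78D2, a flavonoid glucosyltransferase (3.03 ± 0.13), and CHIL, a chalcone isomerase-like gene (3.02 ± 0.12). All 4 auxin and elongation genes fell (4 adjusted over the list alone), with a mean of -1.59 ± 1.19 (adjusted p = 0.000368), IAA29 by 3.16 on the log2 scale and the auxin-conjugating enzyme gene GH3.3 with a change of -1.84 ± 0.21.

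Of 7 photosystem and Calvin cycle genes 4 rose in wt at 120 min (5 adjusted over the list alone), among them PSBY (0.99 ± 0.15), RCA, the activase of Rubisco (0.82 ± 0.1), and SBPASE (0.69 ± 0.16). The list mean was 0.53 ± 0.34 (adjusted p = 0.00252), not called when the correlation was estimated (adjusted p = 0.204 with an estimated correlation). LHCB4.3 rose by 2.09 ± 0.11, while LHCB4.2 (0.36 ± 0.18) and LHCB4.1 (0.14 ± 0.12) did not pass the test, so 1 of 3 light-harvesting genes was called (1 adjusted over the list alone; list adjusted p = 0.0236, and adjusted p = 0.154 with an estimated correlation). Of 10 tetrapyrrole genes 2 fell (2 adjusted over the list alone), PORB, a protochlorophyllide oxidoreductase (-2.39 ± 0.13), and AT1G74470, geranylgeranyl reductase (-0.44 ± 0.11). The tetrapyrrole list as a whole was not called (adjusted p = 0.702). Of 9 autophagy genes 7 fell (8 adjusted over the list alone), such as ATG8F (-0.6 ± 0.11) and ATG8E (-0.59 ± 0.11), with a list adjusted p = 0.00669 and adjusted p = 0.204 with an estimated correlation. Of 3 singlet-oxygen genes 2 rose (2 adjusted over the list alone), STZ by 2.77 ± 0.21 and AT5G64870 by 0.53 ± 0.14 (list adjusted p = 0.035, and adjusted p = 0.154 with an estimated correlation). Of 5 calcium and touch genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0699).

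Lists with 1 or 2 named members were not tested, and their members in wt at 120 min are given singly. The light-signalling gene HYH rose (1.53 ± 0.2) and FHL fell (-1.78 ± 0.25), and the clock gene GI rose by 2.45 ± 0.11. COR15A, a cold- and abscisic-acid-responsive gene, rose by 3.63 ± 0.33, the carotenoid-cyclase gene LYC by 0.57 ± 0.11 and EX1, of the plastid protease list, by 0.41 ± 0.12. EIN3, of ethylene signalling, fell (-0.5 ± 0.15), and so did SAG101 of the salicylate list (-0.4 ± 0.14), whereas WRKY53 (0.05 ± 0.19) did not pass the test. The heat-shock genes were AT1G53540, which rose by 1.1 ± 0.2, and ATHSP22.0 with -0.37 ± 0.14 (adjusted p = 0.0588). The oxidative-stress gene AT2G21640 (0.14 ± 0.16), the iron genes PYE (0.25 ± 0.17) and BHLH101 (0.1 ± 0.16), the seed-reserve gene ICL (-0.14 ± 0.14) and the reference genes AT4G34270 (-0.22 ± 0.09) and AT2G28390 (-0.2 ± 0.1) did not pass the test. Of 3 root genes EXPA7 rose (0.54 ± 0.19; 1 adjusted over the list alone) and the root list was not called (adjusted p = 0.702).

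In all, 6828 probe sets were called in wt at 120 min, 2644 higher and 4184 lower, 1473 of them at least 2-fold. Scaling to the reference genes moved the median of all probe sets from -0.03 to 0.18, and the share of higher calls from 38.7% to 71.9%.

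In fc2 at 30 min the small heat-shock protein genes AT1G54050 (4.74 ± 0.24, n = 2 arrays per group) and AT5G51440 (3.09 ± 0.3), the immunophilin gene AT5G48570 (3.7 ± 0.39), STZ (3.56 ± 0.21) and the DnaJ gene AT2G20560 (3.13 ± 0.25) rose most. IAA29 (-2.89 ± 0.16), AT3G05730 (-2.76 ± 0.36), AT3G53250 (-1.71 ± 0.2), AT4G36010 (-1.53 ± 0.16) and P1R3 (-1.49 ± 0.15) fell most. Among the 5 calcium and touch genes CML38 and CML37 rose (2 adjusted over the list alone; list adjusted p = 0.00367, and adjusted p = 0.125 with an estimated correlation). Of 4 auxin and elongation genes IAA29 fell (2 adjusted over the list alone; list adjusted p = 3.78e-05). There were 672 called probe sets, 427 higher and 245 lower, 244 of them at least 2-fold. The count was 382 without replicate 1 of dark fc2, 383 without its replicate 2, 436 without replicate 1 of fc2 at 30 min, 404 without its replicate 2 and 410 without the seed-richer arrays.

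After 120 min in fc2, AT1G53540 rose by 6.59 ± 0.2 and AT1G54050 by 5.82 ± 0.24, both small heat-shock protein genes, as are AT5G51440 (5.16 ± 0.3) and AT1G52560 (5.07 ± 0.22). AT1G48100 rose by 5.49 ± 0.16. The falls were led by AT3G05730 (-4.66 ± 0.36), IAA29 (-3.43 ± 0.16), AT4G25260 (-2.49 ± 0.12), the kinase gene WAG2 (-2.3 ± 0.19) and AT3G53250 (-2.21 ± 0.2). Among the 10 tetrapyrrole genes 8 fell (8 adjusted over the list alone), such as PORB (-0.77 ± 0.13) and GSA1 (-0.61 ± 0.1), with a list adjusted p = 0.00102 and adjusted p = 0.132 with an estimated correlation. Of 5 calcium and touch genes 4 rose (4 adjusted over the list alone), CML37 by 3.34 ± 0.19 and CML38 by 2.45 ± 0.19 (list adjusted p = 4.41e-05, and adjusted p = 0.0464 with an estimated correlation). Seed-maturation genes averaged 6.54 and 7.63 at 120 min and 5.84 and 5.84 in the dark. In all 5518 probe sets were called, 2409 higher and 3109 lower, 1181 of them at least 2-fold, and 2347 higher and 2169 lower with reference-gene scaling.

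In flu the first 30 min of light brought called changes in 10677 probe sets, 5384 higher and 5293 lower, 2349 of them at least 2-fold. With the spread of each array as a covariate, chosen after the data were seen, there were 3042 higher and 3162 lower. STZ (2.84 ± 0.21, n = 2 arrays per group), AT4G27280 (2.75 ± 0.17), AT5G19240 (2.74 ± 0.19), the U-box ubiquitin ligase gene PUB19 (2.73 ± 0.22) and AT1G27461 (2.68 ± 0.56) rose most. AT3G05730 (-5.2 ± 0.36), AT5G44440 (-4.0 ± 0.15), AT5G55620 (-3.49 ± 0.19), AT5G62280 (-3.22 ± 0.33) and AT1G15260 (-3.13 ± 0.13) fell most. All 7 photosystem and Calvin cycle genes fell (7 adjusted over the list alone), PRK, phosphoribulokinase, with -1.88 ± 0.17 (list adjusted p = 0.000278, and adjusted p = 0.173 with an estimated correlation). Of 10 tetrapyrrole genes 9 fell and 1 rose (9 and 1 adjusted over the list alone; list adjusted p = 2.86e-06, and adjusted p = 0.12 with an estimated correlation). Among the 9 autophagy genes 6 rose (6 adjusted over the list alone), APG8A by 1.05 ± 0.1 (list adjusted p = 0.0027, and adjusted p = 0.173 with an estimated correlation). The seed-maturation mean was 9.28 and 9.02 at 30 min and 8.71 and 8.48 in the dark. With reference-gene scaling the median moved from 0.06 to 0.33, and the share of higher calls from 50.4% to 76.2%.

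After 120 min in flu, GRX480, a glutaredoxin gene, rose by 5.12 ± 0.19, AR781 by 4.76 ± 0.31, AT5G19240 by 4.34 ± 0.19, AT1G53540 by 4.33 ± 0.2 and AT2G18210 by 4.29 ± 0.14. AT3G05730 (-5.63 ± 0.36), AT5G48490 (-4.68 ± 0.15), the response regulator RR16 (-4.58 ± 0.17), AT5G44440 (-4.48 ± 0.15) and TROL, a thylakoid rhodanese-like protein (-4.23 ± 0.22), fell most. All 7 photosystem and Calvin cycle genes were lower than in the dark (7 adjusted over the list alone), with a mean of -3.14 ± 0.52 (list adjusted p = 3.89e-08), as were 8 of 10 tetrapyrrole genes (8 adjusted over the list alone; list adjusted p = 4.56e-07). All 5 calcium and touch genes rose (5 adjusted over the list alone), with a mean of 2.84 ± 1.27 (list adjusted p = 0.00021). In all 10246 probe sets were called, 5391 higher and 4855 lower, 3834 of them at least 2-fold. Scaling to the reference genes moved the median from 0.01 to 0.17 and the share of higher calls from 52.6% to 65.4%.

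In fc1 at 30 min AR781 (3.81 ± 0.31, n = 2 arrays per group), STZ (3.69 ± 0.21), AT5G48570 (3.59 ± 0.39), AT5G39670 (3.4 ± 0.26) and the DnaJ gene AT2G20560 (3.19 ± 0.25) rose most. IAA29 (-3.11 ± 0.16), EXO (-2.49 ± 0.1), AT3G53250 (-2.3 ± 0.2), AT5G62280 (-1.98 ± 0.33) and AT4G36010 (-1.92 ± 0.16) fell most. Among the 5 calcium and touch genes 4 rose (4 adjusted over the list alone), AT3G01830 by 3.11 ± 0.25 and CML37 by 2.5 ± 0.19, and the list was called (adjusted p = 5.67e-08). In all 1605 probe sets were called, 817 higher and 788 lower, 469 of them at least 2-fold. The count was 1065 without replicate 2 of dark fc1 and 1013 without replicate 2 of fc1 at 30 min. With reference-gene scaling the share of higher calls went from 50.9% to 63.9%.

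After 120 min in fc1, AT5G42760 (6.46 ± 0.14), AT1G48100 (5.48 ± 0.16), AT1G60590 (5.34 ± 0.17), AT5G51440 (4.91 ± 0.3) and AT3G56290 (4.88 ± 0.21) rose most, and AT2G34020 (-3.5 ± 0.12), AT5G02540 (-3.36 ± 0.25), IAA29 (-3.31 ± 0.16), AT5G02580 (-3.14 ± 0.13) and AT4G11610 (-3.13 ± 0.16) fell most. All 4 flavonoid genes rose (4 adjusted over the list alone; list adjusted p = 4.55e-05), UGT78D2 by 4.01 ± 0.13 and CHIL by 3.59 ± 0.12. Of 7 photosystem and Calvin cycle genes 5 rose (5 adjusted over the list alone), PSBY by 1.27 ± 0.15 and RCA by 1.03 ± 0.1 (list adjusted p = 0.000357, and adjusted p = 0.135 with an estimated correlation). All 3 singlet-oxygen genes rose (3 adjusted over the list alone; list adjusted p = 0.000611), among them AT5G64870 by 1.98 ± 0.14. Seed-maturation genes averaged 7.64 and 5.28 at 120 min and 8.31 and 8.43 in the dark. In all 7641 probe sets were called, 3395 higher and 4246 lower, 1867 of them at least 2-fold. With reference-gene scaling the median moved from -0.01 to 0.25, and the share of higher calls from 44.4% to 79.1%.

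Each mutant was compared with wt at 0 min, before any light. In fc2, 8 probe sets were called, 4 higher and 4 lower, 7 of them at least 2-fold. RR16, a response regulator of cytokinin signalling (AT2G40670), was higher (1.58 ± 0.17, n = 2 arrays per group, adjusted p = 0.000386), as was AT3G49960 (1.05 ± 0.18). AT4G07820 (-1.92 ± 0.21), LEA4-5, a late embryogenesis abundant protein gene (-1.73 ± 0.27), AT1G43590 (-1.58 ± 0.16) and RSU1 (-0.7 ± 0.12) were lower. The mean of the seed-maturation genes was 5.84 and 5.84 on the fc2 arrays and 8.14 and 7.36 on those of wt. The calls of AT3G49960 and RSU1 were lost with reference-gene scaling and that of RSU1 also with equal spread on all arrays, and the count was 3 without replicate 1 of dark wt, 4 without its replicate 2, 3 without either dark fc2 array and 4 without dim probe sets. Without the seed-richer arrays, an alternative chosen after the data were seen, it was 51, with 8 higher and 43 lower. With equal spread the share of higher calls went from 50% to 62.5%.

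No member of the 9 lists fixed in advance passed the test in fc2 at 0 min over all probe sets. None of 9 autophagy genes was called singly (1 lower adjusted over the list alone), and their mean of -0.22 ± 0.1 was called as a list (adjusted p = 4.73e-06, and adjusted p = 0.0825 with an estimated correlation). None of 10 tetrapyrrole genes (0 adjusted over the list alone) or 4 flavonoid genes (1 higher adjusted over the list alone) was called, and their means of 0.12 ± 0.12 and 0.23 ± 0.19 were called as lists (adjusted p = 0.00544 and 0.00964). With an estimated correlation neither was called (adjusted p = 0.206 and 0.0825 with an estimated correlation).

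In flu at 0 min RR16 was higher by 3.79 ± 0.17 (n = 2 arrays per group, adjusted p = 3.5e-10) and ASPGB1, an asparaginase gene (AT3G16150), by 2.41 ± 0.11, followed by AT3G09380 (2.19 ± 0.2), AT2G44970 (2.14 ± 0.16) and the nitrate transporter gene AT3G21670 (2.0 ± 0.21). AT3G16750 (-2.91 ± 0.19), AT3G19515 (-2.43 ± 0.22), AT5G04120 (-1.88 ± 0.16), AT3G21770 (-1.88 ± 0.1) and AT5G44580 (-1.84 ± 0.14) were lowest relative to wt. Of 3 light-harvesting genes 2 were lower (2 adjusted over the list alone), LHCB4.2 with -1.34 ± 0.18 and LHCB4.3 with -0.54 ± 0.11 (list adjusted p = 0.000743). Of 4 flavonoid genes CHIL (0.91 ± 0.12) and UGT78D2 (0.56 ± 0.13) were higher (2 adjusted over the list alone; list adjusted p = 0.00125). Of 9 autophagy genes 2 were lower (8 adjusted over the list alone), ATG8B with -0.47 ± 0.12 and APG8H with -0.41 ± 0.09 (list adjusted p = 1.5e-06). Among the 10 tetrapyrrole genes GSA1 was higher (0.49 ± 0.1; 4 adjusted over the list alone; list adjusted p = 0.0192, and adjusted p = 0.292 with an estimated correlation). COR15A (1.62 ± 0.33) and AT2G21640 (1.01 ± 0.16) were higher. The seed-maturation mean was 8.71 and 8.48 in flu and 8.14 and 7.36 in wt.

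In flu at 0 min 738 probe sets were called, 361 higher and 377 lower, 85 of them at least 2-fold. The count was 180 without replicate 1 of dark wt, 312 (170 higher and 142 lower) without its replicate 2, 276 (165 higher and 111 lower) without replicate 1 of dark flu and 378 without its replicate 2. With the array-spread covariate it was 1169 (626 higher and 543 lower). Reference-gene scaling took the share of higher calls from 48.9% to 28.9%.

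In fc1 at 0 min AT2G44970 was higher by 2.29 ± 0.16 (n = 2 arrays per group, adjusted p = 7.66e-07), AT3G05950 by 1.21 ± 0.21, AT2G16005 by 1.21 ± 0.17, AT3G57470 by 1.2 ± 0.25 and AT5G38700 by 1.13 ± 0.25. AT5G35940 (-2.23 ± 0.16), AT3G29970 (-1.69 ± 0.22), AT5G48490 (-1.33 ± 0.15), AT5G04790 (-0.95 ± 0.19) and AT4G04460 (-0.86 ± 0.18) were lower. Of 4 flavonoid genes CHIL was lower (-0.79 ± 0.12; 2 adjusted over the list alone), and of 9 autophagy genes ATG8B (-0.51 ± 0.12; 1 adjusted over the list alone), and none of the 9 tested lists was called. All 3 light-harvesting and 4 of 7 photosystem and Calvin cycle genes were lower when adjusted over the list alone (0 over all probe sets; list adjusted p = 0.0596 for both). With equal spread these lists and autophagy were called (adjusted p = 0.0182, 0.0138 and 0.0182). Seed-maturation genes averaged 8.31 and 8.43 in fc1 and 8.14 and 7.36 in wt. In all 608 probe sets were called, 290 higher and 318 lower, 31 of them at least 2-fold. The count was 7 without replicate 1 of dark wt, 154 without its replicate 2, 39 without replicate 1 of dark fc1 and 15 without its replicate 2. It was 1074 without dim probe sets, 999 with trend and robust moderation, 294 without the seed-richer arrays and 316 with the array-spread covariate. No array of 0 min was among the seed-richer ones, so leaving those out changed only the pooled spread here. Scaling to the reference genes moved the median from -0.04 to -0.26, the count to 3914 and the share of higher calls from 47.7% to 4.8%.

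At 30 min the small heat-shock protein genes AT1G53540 (2.12 ± 0.2, n = 2 arrays per group, adjusted p = 4.61e-06), ATHSP22.0 (AT4G10250, 1.61 ± 0.14) and AT1G54050 (1.51 ± 0.24) were higher in fc2 than in wt, with AT5G62280 (1.61 ± 0.33) and EXO (1.6 ± 0.1). AT5G42760 (-2.74 ± 0.14, adjusted p = 1.04e-08), AT3G52740, an inhibitor of cryptochromes named BIC1 (-2.02 ± 0.14), AT1G43590 (-2.01 ± 0.16), AT3G05730 (-2.01 ± 0.36) and AT3G30460 (-1.86 ± 0.22) were lower. Of 4 flavonoid genes UGT78D2 was lower (-0.91 ± 0.13; 1 adjusted over the list alone; list adjusted p = 0.0465, and adjusted p = 0.208 with an estimated correlation). Of 5 calcium and touch genes AT3G01830 was lower (-1.36 ± 0.25; 2 adjusted over the list alone; list adjusted p = 0.212), and of 3 light-harvesting genes LHCB4.3 (-0.53 ± 0.11; 1 adjusted over the list alone; list adjusted p = 0.0769, and adjusted p = 0.0438 with equal spread). None of 10 tetrapyrrole genes was called (0 adjusted over the list alone), with a list mean of 0.17 ± 0.17 (adjusted p = 0.0128, and adjusted p = 0.339 with an estimated correlation). STZ (-0.01 ± 0.21) and AT5G64870 (0.04 ± 0.14) did not pass the test. The seed-maturation mean was 7.95 and 5.58 in fc2 and 8.54 and 8.79 in wt.

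At 30 min 337 probe sets were called in fc2, 118 higher and 219 lower, 83 of them at least 2-fold. The count was 223 without replicate 1 of wt at 30 min, 821 without its replicate 2 (530 higher and 291 lower, so that the larger side turned), 143 without replicate 1 of fc2 at 30 min, 189 without its replicate 2 and 196 without the seed-richer arrays. The light response itself differed from that of wt in 98 probe sets, 40 higher and 58 lower, among them AT1G53540 (2.79 ± 0.28), EXO (1.78 ± 0.14), ATHSP22.0 (1.7 ± 0.2), AT1G54050 (1.59 ± 0.33) and AT1G76600 (1.43 ± 0.17). On the other side stood AT5G42760 (-2.42 ± 0.2), AT3G52740 (-2.0 ± 0.2), AT3G30460 (-1.9 ± 0.3), AT3G56260 (-1.55 ± 0.16) and AT3G49960 (-1.45 ± 0.25). This count was 53 and 50 without replicate 1 or 2 of dark wt, 50 and 48 without replicate 1 or 2 of dark fc2, 62 and 59 without replicate 1 or 2 of fc2 at 30 min, and 46 without the seed-richer arrays.

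At 120 min AT1G53540 was higher in fc2 than in wt by 4.82 ± 0.2 (n = 2 arrays per group, adjusted p = 1.61e-11), ATHSP22.0 by 4.52 ± 0.14, AT1G52560 by 4.51 ± 0.22, the DnaJ gene AT1G71000 by 4.36 ± 0.16 and AT5G37670 by 4.11 ± 0.19. AT2G27420 (-3.36 ± 0.23), AT5G42760 (-3.21 ± 0.14), AT3G05730 (-3.17 ± 0.36), AT1G60590 (-3.17 ± 0.17) and AT1G76110 (-2.7 ± 0.18) were lower. Of these, AT5G42760 and AT1G60590 were among the 5 largest rises of wt in the same time. Among the 5 calcium and touch genes 3 were higher (4 adjusted over the list alone), AT1G76640, the calmodulin-like CML39, by 2.9 ± 0.23, CML37 by 1.25 ± 0.19 and CML38 by 0.87 ± 0.19. The list mean was 1.18 ± 1.02 (adjusted p = 0.00018, and adjusted p = 0.0533 with an estimated correlation).

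All 3 light-harvesting genes were lower in fc2 at 120 min (3 adjusted over the list alone), LHCB4.3 with -1.74 ± 0.11, LHCB4.2 with -0.77 ± 0.18 and LHCB4.1 with -0.65 ± 0.12 (list mean -1.06 ± 0.6, adjusted p = 7.56e-05). Of 7 photosystem and Calvin cycle genes 6 were lower (6 adjusted over the list alone), such as PRK (-0.99 ± 0.17), SBPASE (-0.99 ± 0.16) and RCA (-0.95 ± 0.1). The list mean was -0.77 ± 0.27 (adjusted p = 1.46e-06, and adjusted p = 0.0618 with an estimated correlation). Of 4 flavonoid genes 3 were lower (3 adjusted over the list alone), UGT78D1 with -2.0 ± 0.23, CHIL with -1.59 ± 0.12 and DFR with -1.1 ± 0.28 (list mean -1.24 ± 0.75, adjusted p = 7.56e-05). Of 10 tetrapyrrole genes 5 were lower and 1 higher (6 and 1 adjusted over the list alone), with a list adjusted p = 0.0607 and adjusted p = 0.027 with equal spread. HEME2, uroporphyrinogen decarboxylase, had -0.68 ± 0.13 and CHLM, magnesium protoporphyrin methyltransferase, -0.48 ± 0.08, whereas PORB was higher by 1.58 ± 0.13.

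Among the 9 autophagy genes 6 were higher in fc2 at 120 min (8 adjusted over the list alone), among them ATG8E (0.49 ± 0.11) and APG8H (0.45 ± 0.09), with a list adjusted p = 0.000154 and adjusted p = 0.0922 with an estimated correlation. Of 3 singlet-oxygen genes STZ was higher (1.47 ± 0.21) and AT5G64870 lower (-0.46 ± 0.14; 1 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.437). Of 4 auxin and elongation genes GH3.3 (1.12 ± 0.21) and WES1 (0.53 ± 0.11) were higher (2 adjusted over the list alone; list adjusted p = 0.227). AT2G21640 was higher by 1.31 ± 0.16, and COR15A (-1.23 ± 0.33), LYC (-0.62 ± 0.11) and EX1 (-0.44 ± 0.12) were lower.

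At 120 min 3830 probe sets were called in fc2, 2157 higher and 1673 lower, 623 of them at least 2-fold. The count was 2382 without replicate 1 of fc2 at 120 min and 2410 (1159 higher and 1251 lower) without its replicate 2. Without the seed-richer arrays it was 1838, with 744 higher and 1094 lower. With reference-gene scaling the median moved from 0.01 to -0.18, and the share of higher calls from 56.3% to 17%. The light response differed from that of wt in 2047 probe sets, 1058 higher and 989 lower, led by AT1G53540 (5.49 ± 0.28), ATHSP22.0 (4.61 ± 0.2), AT1G52560 (4.55 ± 0.31), AT1G71000 (4.46 ± 0.23) and AT5G37670 (4.29 ± 0.27). AT1G60590 (-3.48 ± 0.24), AT3G05730 (-3.43 ± 0.51), AT2G27420 (-3.36 ± 0.32), AT1G76110 (-2.95 ± 0.26) and AT5G42760 (-2.89 ± 0.2) led the other side. The count was 1353 (644 higher) without replicate 1 of dark wt, 1330 (621 higher) without replicate 1 of dark fc2 and 1255 (588 higher) without its replicate 2, with the lower side larger in each. Reference-gene scaling moved the median of the interaction from 0.03 to -0.14 and the share of higher calls from 51.7% to 21.1%.

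**Figure D3:**
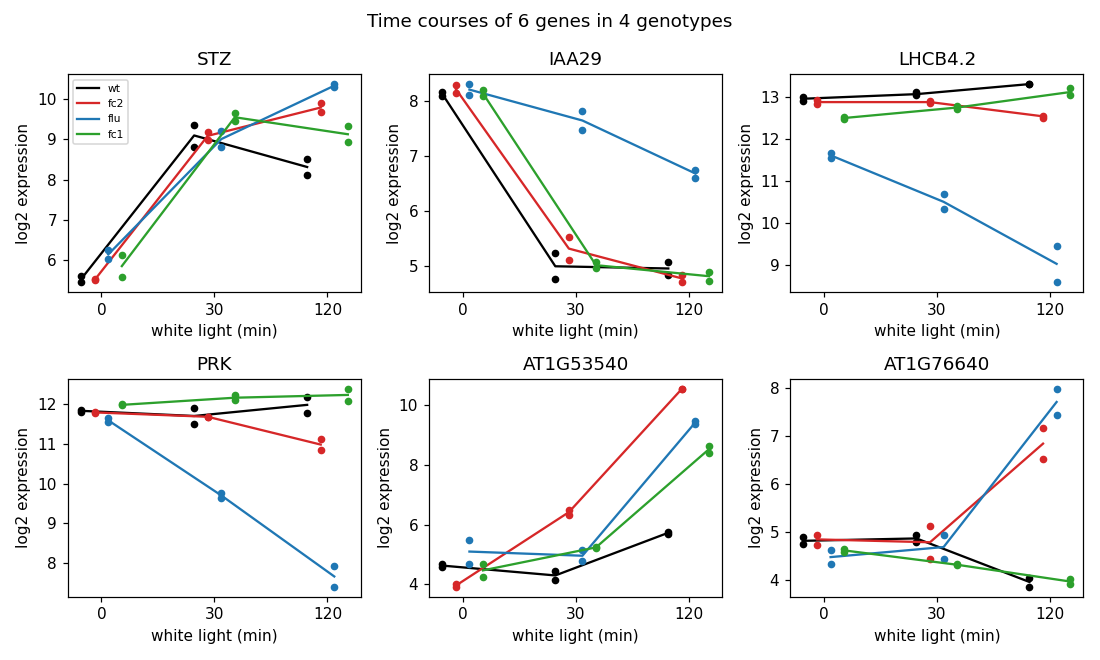
Log2 expression (vertical axis) of STZ, IAA29, LHCB4.2, PRK, AT1G53540 and AT1G76640 at 0, 30 and 120 min of light (evenly spaced on the horizontal axis) in wt, fc2, flu and fc1, with 1 point per array and lines through the group means. At 120 min AT1G53540 was higher than in wt by 4.82 in fc2, 3.7 in flu and 2.8 in fc1, and LHCB4.2 differed from wt by -4.3 in flu.

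At 30 min ASPGB1 (3.65 ± 0.11, n = 2 arrays per group, adjusted p = 3.97e-13), RR16 (2.95 ± 0.17), IAA29 (2.64 ± 0.16), AT1G27461 (2.29 ± 0.56) and AT3G09380 (2.01 ± 0.2) were higher in flu than in wt. AT3G05730 (-5.08 ± 0.36), AT1G64500 (-4.31 ± 0.16), AT5G44440 (-4.16 ± 0.15, adjusted p = 2.2e-12), AT5G55620 (-4.12 ± 0.19) and AT5G44580 (-3.33 ± 0.14) were lower. The seed-maturation mean was 9.28 and 9.02 in flu and 8.54 and 8.79 in wt.

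All 7 photosystem and Calvin cycle genes were lower in flu at 30 min (7 adjusted over the list alone), such as PRK (-2.0 ± 0.17), SBPASE (-1.51 ± 0.16) and RCA (-1.02 ± 0.1). The list mean was -1.1 ± 0.55 (adjusted p = 1.22e-05, and adjusted p = 0.0986 with an estimated correlation). Among the 10 tetrapyrrole genes 9 were lower (9 lower and 1 higher adjusted over the list alone), with a mean of -0.85 ± 0.57 (adjusted p = 5.7e-06), among them AT1G74470 (-1.63 ± 0.11) and HEME1 (-1.29 ± 0.14). All 3 light-harvesting genes were lower (3 adjusted over the list alone; list adjusted p = 0.00137), LHCB4.2 with -2.57 ± 0.18 and LHCB4.1 with -1.17 ± 0.12. Of 4 flavonoid genes 3 were lower (3 adjusted over the list alone; list adjusted p = 0.0111), UGT78D2 with -2.41 ± 0.13. The light-signalling gene HYH was lower (-2.05 ± 0.2).

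Of 4 auxin and elongation genes 3 were higher in flu at 30 min and 1 lower (3 and 1 adjusted over the list alone), among them IAA29 and GH3.3 (1.73 ± 0.21). The list adjusted p was 0.0222, with adjusted p = 0.0986 with an estimated correlation and adjusted p = 0.055 with reference-gene scaling. Of 9 autophagy genes 5 were higher (6 adjusted over the list alone), APG8A by 0.88 ± 0.1 and ATG8B by 0.71 ± 0.12 (list adjusted p = 0.0132, and adjusted p = 0.256 with an estimated correlation). Of 3 singlet-oxygen genes AT5G64870 was higher (1.92 ± 0.14; 1 adjusted over the list alone), while STZ had -0.09 ± 0.21 and AT3G28580 -0.02 ± 0.1, and the list was not called (adjusted p = 0.281). Of 5 calcium and touch genes CML37 (-1.04 ± 0.19) and AT3G01830 (-1.29 ± 0.25) were lower and CML23 (0.66 ± 0.21) higher (2 and 1 adjusted over the list alone; list adjusted p = 0.241). WRKY53 was higher by 1.28 ± 0.19, AT1G53540 by 0.66 ± 0.2, and ATHSP22.0 was lower (-0.77 ± 0.14).

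At 30 min 8983 probe sets were called in flu, 4755 higher and 4228 lower, 1554 of them at least 2-fold, and 5921 (2849 higher and 3072 lower) without replicate 2 of wt at 30 min. With the array-spread covariate there were 2381 higher and 2421 lower. Scaling to the reference genes moved the median from 0.07 to 0.33, and the share of higher calls from 52.9% to 80.7%, and the reference gene AT2G28390 was itself lower in flu (-0.57 ± 0.1, adjusted p = 0.000248). The light response differed from that of wt in 6201 probe sets, 3084 higher and 3117 lower. IAA29 (2.56 ± 0.23), AT2G18210 (2.35 ± 0.2), AT3G48370 (2.12 ± 0.24), AT5G64870 (1.83 ± 0.2) and TRI (1.76 ± 0.19) led the higher side. AT3G05730 (-4.7 ± 0.51), AT1G64500 (-4.16 ± 0.23), AT5G55620 (-3.96 ± 0.27), AT5G44440 (-3.75 ± 0.21) and AT5G48570 (-3.34 ± 0.55) led the lower side. With reference-gene scaling the median of the interaction moved from 0.06 to 0.4, the count to 9483 and the share of higher calls from 49.7% to 82.8%.

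At 120 min ASPGB1 (4.3 ± 0.11, n = 2 arrays per group, adjusted p = 5.24e-15), GRX480 (AT1G28480, 3.86 ± 0.19), AT1G76640 (3.76 ± 0.23), AT2G18210 (3.73 ± 0.14) and AT1G53540 (3.7 ± 0.2) were higher in flu than in wt. AT1G60590 (-5.82 ± 0.17), AT5G42760 (-5.64 ± 0.14), AT5G48490 (-5.54 ± 0.15), AT1G27480 (-4.97 ± 0.19) and CaS, a thylakoid calcium-sensing protein (-4.83 ± 0.12), were lower. RR16, higher at 0 and 30 min, was lower at 120 min (-1.35 ± 0.17). All 7 photosystem and Calvin cycle genes were lower (7 adjusted over the list alone), with a mean of -3.78 ± 0.48 (adjusted p = 5.99e-10), for example SBPASE (-4.35 ± 0.16) and RCA (-3.51 ± 0.1). All 3 light-harvesting genes were lower (3 adjusted over the list alone; list adjusted p = 6.76e-05), LHCB4.2 with -4.3 ± 0.18, LHCB4.1 with -3.29 ± 0.12 and LHCB4.3 with -2.24 ± 0.11. Of 10 tetrapyrrole genes 8 were lower and 1 higher (8 and 1 adjusted over the list alone), with a mean of -1.75 ± 1.37 (adjusted p = 6.23e-07), AT1G74470 with -3.57 ± 0.11 and CHLI2, a subunit of magnesium chelatase, with -3.29 ± 0.14. All 4 flavonoid genes were lower (4 adjusted over the list alone; list adjusted p = 0.000401), CHIL with -4.03 ± 0.12 and UGT78D1 with -3.59 ± 0.23.

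All 5 calcium and touch genes were higher in flu at 120 min (5 adjusted over the list alone), AT3G01830 by 2.87 ± 0.25 and CML37 by 1.92 ± 0.19 (list mean 2.15 ± 1.16, adjusted p = 0.001, and adjusted p = 0.0603 with an estimated correlation). All 3 singlet-oxygen genes were higher (3 adjusted over the list alone), AT5G64870 by 2.2 ± 0.14, STZ by 2.01 ± 0.21 and AT3G28580 by 0.25 ± 0.1 (list adjusted p = 0.0204, and adjusted p = 0.0629 with an estimated correlation). Among the 9 autophagy genes 8 were higher (8 adjusted over the list alone), APG8A by 1.19 ± 0.1, ATG8G by 1.13 ± 0.12 and ATG8B by 1.07 ± 0.12 (list adjusted p = 0.000489, and adjusted p = 0.0915 with an estimated correlation). Of 4 auxin and elongation genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone; list adjusted p = 0.153), GH3.3 by 2.78 ± 0.21 and EXPA8 with -1.59 ± 0.12. COR15A was lower (-3.86 ± 0.33), and WRKY53 (1.08 ± 0.19), ATHSP22.0 (0.75 ± 0.14), ICL (0.73 ± 0.14), EIN3 (0.55 ± 0.15) and the root gene EXPA7 (0.75 ± 0.19) were higher. The mean of the seed-maturation genes was 9.62 and 7.61 in flu at 120 min and 5.5 and 7.88 in wt.

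At 120 min 10354 probe sets were called in flu, 6311 higher and 4043 lower, 3433 of them at least 2-fold. Scaling to the reference genes moved the median from 0.06 to -0.07 and the share of higher calls from 61% to 48.3%, and the reference gene AT4G34270 was itself higher (0.35 ± 0.09, adjusted p = 0.00394). The light response differed from that of wt in 8503 probe sets, 5106 higher and 3397 lower. AT2G18210 (4.18 ± 0.2), AT1G76640 (4.11 ± 0.33), GRX480 (3.88 ± 0.26), AT5G19110 (3.39 ± 0.2) and AR781 (3.27 ± 0.44) led the higher side. AT3G21670 (-6.05 ± 0.3), AT1G60590 (-6.03 ± 0.24), AT5G42760 (-5.62 ± 0.2), COR15A (-5.47 ± 0.47) and AT5G48490 (-5.31 ± 0.21) led the lower side.

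At 30 min AT2G32140 (2.29 ± 0.17, n = 2 arrays per group, adjusted p = 5.78e-07), AT5G64870 (1.94 ± 0.14), CML23 (AT1G66400, 1.88 ± 0.21), AT3G05900 (1.88 ± 0.59) and DLAH (AT1G30370, 1.82 ± 0.18) were higher in fc1 than in wt. AT1G27461 (-2.25 ± 0.56), AT5G07330 (-2.21 ± 0.62), AT3G54940 (-2.2 ± 0.68), AT3G02480 (-2.17 ± 0.49) and AT5G35940 (-2.06 ± 0.16) were lower. Seed-maturation genes averaged 8.83 and 5.57 on the fc1 arrays and 8.54 and 8.79 on those of wt, and AT5G07330 stood at 6.66 and 5.08 in fc1 and at 7.68 and 8.49 in wt. Of 3 singlet-oxygen genes 1 was higher (1 adjusted over the list alone), AT5G64870, with STZ at 0.46 ± 0.21 (list adjusted p = 0.0438, and adjusted p = 0.188 with an estimated correlation). Among the 5 calcium and touch genes 2 were higher (3 higher and 1 lower adjusted over the list alone), CML23 and AT3G01830 (1.43 ± 0.25), with a list adjusted p = 0.0451 and adjusted p = 0.394 with an estimated correlation. WRKY53 (1.79 ± 0.19), AT1G53540 (0.93 ± 0.2), EIN3 (0.74 ± 0.15), SAG101 (0.58 ± 0.14) and GI (0.37 ± 0.11) were higher. No photosystem, Calvin cycle, tetrapyrrole or flavonoid gene passed the test, and LHCB4.3 was lower (-0.46 ± 0.11). The auxin and elongation list held 2 lower genes of 4 (2 adjusted over the list alone; list adjusted p = 0.222), and the root list 1 higher gene of 3 (1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.907).

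At 30 min 4091 probe sets were called in fc1, 2151 higher and 1940 lower, and 316 of them differed at least 2-fold. With reference-gene scaling there were 1599 higher and 1989 lower. The count was 240 without replicate 1 of wt at 30 min, 1584 without replicate 1 of fc1 at 30 min and 639 (283 higher and 356 lower) without its replicate 2. It was 2324 (1159 higher and 1165 lower) with the seed-maturation genes as a covariate and 1573 without the arrays richer in seed transcripts, both chosen after the data were seen. The light response differed from that of wt in 42 probe sets, 36 higher and 6 lower, among them AT2G32140 (2.31 ± 0.24), DLAH (2.15 ± 0.26), AT2G18210 (1.78 ± 0.2), AT5G64870 (1.74 ± 0.2) and AT1G24140 (1.71 ± 0.24). AT4G11190 (-1.06 ± 0.17), AT4G11210 (-0.95 ± 0.18) and AT5G66390 (-0.86 ± 0.15) were on the lower side, and these 3 calls were lost with reference-gene scaling, which moved the median from 0 to 0.14 and the share of higher calls from 85.7% to 95.8%. This count was 26 without either dark wt array, 26 without replicate 1 of dark fc1, 27 and 67 without replicate 1 or 2 of wt at 30 min, and 22 without replicate 2 of fc1 at 30 min. Without the seed-richer arrays it was 70, with 30 higher and 40 lower.

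At 120 min AT1G53540 (2.8 ± 0.2, n = 2 arrays per group, adjusted p = 8.44e-08), AT1G26380, a berberine-bridge-like oxidase gene (2.78 ± 0.17), AT5G57760 (2.52 ± 0.14), AT3G01830 (2.4 ± 0.25) and AT2G44970 (2.01 ± 0.16) were higher in fc1 than in wt. AT5G35940 (-1.94 ± 0.16), AT3G29970 (-1.65 ± 0.22), AT4G13580 (-1.34 ± 0.11), AT4G11190 (-1.27 ± 0.12) and AT5G47530 (-1.26 ± 0.14) were lower. All 3 singlet-oxygen genes were higher (3 adjusted over the list alone), AT5G64870 by 1.67 ± 0.14, STZ by 0.81 ± 0.21 and AT3G28580 by 0.52 ± 0.1, with a list mean of 1.0 ± 0.6 (adjusted p = 0.000112). Of 5 calcium and touch genes 2 were higher (3 adjusted over the list alone), AT3G01830 and CML37 (1.7 ± 0.19; list adjusted p = 0.000499, and adjusted p = 0.0826 with an estimated correlation). Among the 10 tetrapyrrole genes PORB was higher (0.47 ± 0.13; 3 adjusted over the list alone). The tetrapyrrole list adjusted p was 0.022, with adjusted p = 0.299 with an estimated correlation, adjusted p = 0.0738 with reference-gene scaling and adjusted p = 0.105 with equal spread. Of 9 autophagy genes ATG8B (-0.49 ± 0.12) and APG8A (-0.32 ± 0.1) were lower (3 adjusted over the list alone; list adjusted p = 0.0126, and adjusted p = 0.299 with an estimated correlation). The seed-maturation mean was 7.64 and 5.28 in fc1 and 5.5 and 7.88 in wt at 120 min.

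At 120 min 2055 probe sets were called in fc1, 1268 higher and 787 lower, 231 of them at least 2-fold. It was 229 without the seed-richer arrays and 1042 with the array-spread covariate. The count was 4373 without replicate 1 of wt at 120 min, 469 without its replicate 2, 1354 without replicate 1 of fc1 at 120 min and 544 without its replicate 2. The share of higher calls was 61.7%, and 50.8% with equal spread on all arrays. Reference-gene scaling moved the median from -0.01 to -0.18 and gave 565 higher and 1825 lower calls. The light response differed from that of wt in 223 probe sets, 155 higher and 68 lower, led by AT1G53540 (2.96 ± 0.28), AT1G26380 (2.79 ± 0.25), AT3G16530 (2.5 ± 0.18), AT3G01830 (2.41 ± 0.35) and AT5G57760 (2.13 ± 0.2). AT4G11190 (-1.56 ± 0.17), AT4G13580 (-1.24 ± 0.15), AT4G02090 (-1.15 ± 0.15), AT1G30750 (-1.1 ± 0.12) and AT4G05170 (-1.09 ± 0.16) led the other side. This count was 110 and 147 without replicate 1 or 2 of dark wt, 132 and 128 without replicate 1 or 2 of dark fc1 and 143 without replicate 2 of fc1 at 120 min, 108 without the seed-richer arrays and 351 with the array-spread covariate, and reference-gene scaling moved its share of higher calls from 69.5% to 80.9%.

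The mutants fc2 and flu were also compared directly. At 30 min AT5G44440 (3.96 ± 0.15, n = 2 arrays per group, adjusted p = 1.02e-11), AT5G48570 (3.48 ± 0.39), AT5G55620 (3.12 ± 0.19), AT3G05730 (3.07 ± 0.36) and AT1G64500 (2.87 ± 0.16) were higher in fc2. AT1G54870 (-4.6 ± 1.1), the oleosin gene AT3G01570 (-4.56 ± 1.17), LCR67 (-4.52 ± 1.43), AT1G27461 (-4.38 ± 0.56) and AT1G04560 (-4.22 ± 0.92) were lower. Seed-maturation genes averaged 7.95 and 5.58 in fc2 and 9.28 and 9.02 in flu, and AT3G01570 stood at 8.07 and 5.48 in fc2 and at 11.47 and 11.19 in flu. All 7 photosystem and Calvin cycle genes were higher in fc2 (7 adjusted over the list alone), PRK by 1.97 ± 0.17 (list adjusted p = 1.89e-05, and adjusted p = 0.136 with an estimated correlation). Of 10 tetrapyrrole genes 9 were higher (9 higher and 1 lower adjusted over the list alone), AT1G74470 by 1.62 ± 0.11 (list adjusted p = 1.15e-06, and adjusted p = 0.101 with an estimated correlation). Both heat-shock genes were higher, ATHSP22.0 by 2.38 ± 0.14 and AT1G53540 by 1.45 ± 0.2, and AT5G64870 was lower (-1.88 ± 0.14). In all 10638 probe sets were called, 5002 higher and 5636 lower, 1861 of them at least 2-fold, and 2032 higher and 1890 lower with the array-spread covariate. With reference-gene scaling the median moved from -0.08 to -0.35, and the share of higher calls from 47% to 21.4%.

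At 120 min AT5G48490 (4.51 ± 0.15, n = 2 arrays per group, adjusted p = 3.07e-13), AT5G44440 (3.87 ± 0.15), TROL (3.82 ± 0.22), ATHSP22.0 (3.77 ± 0.14) and AT5G38520 (3.61 ± 0.17) were higher in fc2 than in flu. AT3G01570 (-4.23 ± 1.17), ASPGB1 (-4.05 ± 0.11), AT5G66780 (-3.23 ± 0.68), AT2G18210 (-3.21 ± 0.14) and AT5G19110 (-3.1 ± 0.14) were lower, and the seed-maturation mean was 6.54 and 7.63 in fc2 and 9.62 and 7.61 in flu. All 7 photosystem and Calvin cycle genes were higher in fc2 (7 adjusted over the list alone), with a mean of 3.02 ± 0.39 (adjusted p = 1.25e-11), and so were all 3 light-harvesting genes (3 adjusted over the list alone; list adjusted p = 0.000259). Among the 10 tetrapyrrole genes 8 were higher (8 adjusted over the list alone; list adjusted p = 1.45e-08), PORB by 2.92 ± 0.13, and of 4 flavonoid genes 3 (3 adjusted over the list alone; list adjusted p = 0.00577). Among the 9 autophagy genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone), ATG8B with -0.9 ± 0.12 (list adjusted p = 0.0127, and adjusted p = 0.217 with an estimated correlation). Of 3 singlet-oxygen genes 2 were lower (2 adjusted over the list alone), AT5G64870 with -2.66 ± 0.14 and STZ with -0.55 ± 0.21 (list adjusted p = 0.0499, and adjusted p = 0.135 with an estimated correlation). That call was also lost with the mean of all probe sets, reference-gene scaling, the seed-maturation covariate and equal spread (adjusted p = 0.0502, 0.0536, 0.0621 and 0.0539). Among the 5 calcium and touch genes 3 were lower (4 adjusted over the list alone), AT3G01830 with -2.52 ± 0.25 (list adjusted p = 0.033, and adjusted p = 0.198 with an estimated correlation). In all 8321 probe sets were called, 3549 higher and 4772 lower, 2135 of them at least 2-fold.

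Of calls shared by fc2 and flu against wt at 120 min, 1768 were higher in both, 1498 lower in both and 114 opposite. Independent lists of the same sizes would share 612.7 higher and 304.4 lower probe sets. At a change of at least 2-fold, 128 were higher and 369 lower in both, against 16.8 and 32.3 for independent lists. Across probe sets, which are not independent replicates, the changes in the mutants had a correlation of 0.677 and a covariance of 0.229. In 100 simulations of unchanged groups against the same controls the correlation averaged 0.5, the covariance 0.0121 and the overlap of calls 0.01. Unchanged groups give few calls, so that overlap sets no baseline. Both comparisons used the same 2 wt arrays, not split as each part would keep 1, so these may give some of the excess. AT1G53540, AT1G76640 and STZ were higher and AT1G60590, AT5G42760, PRK and CHIL lower in both mutants, while AT5G64870 was higher in flu (2.2 ± 0.14) and lower in fc2 (-0.46 ± 0.14).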

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

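The tests of equal spread, of array spread, of the seed-maturation covariate, of single arrays as a pattern and of lamp warming were chosen only after the data or the result were seen, and the tests of the interactions were planned. The results in the next 3 paragraphs were picked out because the light response of a mutant differed from that of wt by the tested interaction.

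In fc2 the light response differed in 98 probe sets at 30 min and in 2047 at 120 min. Without 1 array in turn the count at 30 min ran from 48 to 94 and at 120 min from 1255 to 2307. At 30 min the interaction of the flavonoid genes averaged -0.54 (1 of 4 members called, 2 adjusted over the list alone, adjusted p = 8.98e-05). At 120 min the interaction was negative for the light-harvesting genes (-0.98, 2 of 3 called), photosystem and Calvin cycle genes (-0.78, 5 of 7), tetrapyrrole genes (-0.22, 4 of 10 lower and 1 higher) and flavonoid genes (-1.46, 2 of 4), among them CHIL (-2.08) and UGT78D1 (-2.25). It was positive for the calcium and touch genes (1.18, 3 of 5), with AT1G76640 at 2.88, and for the autophagy genes (0.59, 6 of 9). Adjusted over the list alone, these counts were 3, 5, 6 and 1, 3, 3 and 9. With an estimated correlation the photosystem and Calvin cycle, tetrapyrrole and calcium and touch lists were not called (adjusted p = 0.0539, adjusted p = 0.206 and adjusted p = 0.0539 with an estimated correlation).

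In flu the light response differed in 6201 probe sets at 30 min and in 8503 at 120 min. At 30 min the interaction was -0.78 for light-harvesting genes (2 of 3 called), -0.99 for photosystem and Calvin cycle genes (5 of 7), -1.01 for tetrapyrrole genes (9 of 10) and -1.48 for flavonoid genes (3 of 4), and it was 1.21 for auxin and elongation genes (3 of 4), with IAA29 at 2.56, and 0.69 for autophagy genes (7 of 9). Adjusted over the list alone, the counts were the same, except for 1 further tetrapyrrole gene that was higher and 8 autophagy genes. With an estimated correlation the light-harvesting, photosystem and Calvin cycle, auxin and autophagy lists were not called (adjusted p = 0.162, adjusted p = 0.121, adjusted p = 0.0887 and adjusted p = 0.0887 with an estimated correlation), nor was light harvesting with equal spread (adjusted p = 0.0952). At 120 min it was -2.63 for light-harvesting genes (3 of 3), -3.67 for photosystem and Calvin cycle genes (7 of 7), -1.91 for tetrapyrrole genes (8 of 10), -2.88 for flavonoid genes (3 of 4), 2.18 for calcium and touch genes (5 of 5) and 1.1 for autophagy genes (8 of 9), with equal counts when adjusted over the list alone. The last 2 lists were not called with an estimated correlation (adjusted p = 0.0594 and adjusted p = 0.0559 with an estimated correlation).

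In fc1 the light response differed in 42 probe sets at 30 min and in 223 at 120 min. Without 1 array in turn the count at 30 min ran from 22 to 67 and at 120 min from 110 to 241. Without the seed-richer arrays they were 70 and 108, and with the array-spread covariate that at 120 min was 351. At 30 min the interaction was 0.28 for flavonoid genes (0 of 4 called), 0.62 for singlet-oxygen genes (1 of 3), with AT5G64870 at 1.74, 0.74 for calcium and touch genes (0 of 5) and 0.14 for autophagy genes (0 of 9), with 2, 1, 3 and 0 when adjusted over the list alone. None of these 4 lists was called with an estimated correlation (adjusted p = 0.0796, adjusted p = 0.0602, adjusted p = 0.0602 and adjusted p = 0.404 with an estimated correlation), the flavonoid list was not called with reference-gene scaling (adjusted p = 0.0593), and the flavonoid and autophagy lists were not called with the seed-maturation covariate (adjusted p = 0.0617 and 0.129). At 120 min it was 0.26 for photosystem and Calvin cycle genes (0 of 7), 0.31 for tetrapyrrole genes (0 of 10), 0.47 for flavonoid genes (1 of 4), 0.81 for singlet-oxygen genes (1 of 3) and 1.1 for calcium and touch genes (2 of 5), with 0, 0, 2, 2 and 3 when adjusted over the list alone. The first 2 of these were not called with an estimated correlation (adjusted p = 0.453 and adjusted p = 0.1 with an estimated correlation), and the first was not called with equal spread (adjusted p = 0.0718).

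Of 3 patterns weighed, chosen from the differences from wt after these were seen, the first was the 4091 probe sets called in fc1 at 30 min, of which 316 differed at least 2-fold. Equal spread on all arrays left 4054 and the spread of each array as a covariate left 3694, which argues against array-wide differences in spread as the main source. Without replicate 1 of wt at 30 min the count was 240 and without its replicate 2 it was 5417, so that array may carry many of the calls. Without replicate 1 or 2 of fc1 at 30 min it was 1584 or 639, so the count also depended on other arrays. With the seed-maturation covariate it was 2324, and seed material and genotype cannot be told apart here because this count fell between the bounds set for the test. A difference by genotype stays open.

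The second pattern was the fall of photosystem and Calvin cycle genes in flu at 30 min. With the seed-maturation covariate their mean was -1.1, as without it, which argues against seed material in place of seedling tissue. An effect of the flu genotype in the light may underlie the fall, as a hypothesis found on the same data. Seed material and other differences between the plants stay open.

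The third pattern was the rise of heat-shock genes in fc2 at 120 min. The mean interaction of AT1G53540 and ATHSP22.0 was 5.05, beside a difference from wt of 4.67. The interaction contains the difference that prompted the test, but warming that acted on both genotypes alike would have raised these genes in wt too, where ATHSP22.0 had -0.37 and AT1G53540 rose by 1.1 at 120 min, against 4.23 and 6.59 in fc2. For these 2 genes this argues against it as the whole cause. AT1G54050 did rise in wt, by 3.15 at 30 min and 1.86 at 120 min, beside an interaction of 3.96 at 120 min, so warming may have had a part in its rise. With the seed-maturation covariate the mean difference of AT1G53540, ATHSP22.0, AT1G52560, AT1G71000, AT5G37670, AT1G54050 and AT2G29500 was 4.22, against 4.21 without it. These 7 genes were chosen after their values were seen, so the comparison covers them alone. An effect of the fc2 genotype is a candidate explanation, and a difference in warming between the plates of the genotypes stays open.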

How the results depend on the processing

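Seed-maturation covariate, seed-richer arrays, equal spread and array spread were chosen after seeing the data, and the rest were planned. Of the list results and named genes tested, 0 reversed, but a reversal was unlikely for genes picked for large changes. The larger side of some counts turned. Where a count moved by over 1.5 times, the cause was not tested, except that leaving out arrays removes samples. With reference-gene scaling 2 of 25 counts moved: fc1 against wt at 0 min from 608 to 3914 and the flu interaction at 30 min from 6201 to 9483. Without the dimmest probe sets, fc2 and fc1 against wt at 0 min went to 4 and 1074, and with trend and robust moderation fc1 at 0 min went to 999. The seed-gene covariate gave 5 for fc2 at 0 min and 2324 for fc1 at 30 min. Without the seed-rich arrays 10 counts moved: 410 for the fc2 light response at 30 min, 51 and 294 for fc2 and fc1 at 0 min, 196 and 1573 for fc2 and fc1 at 30 min, 1838 and 229 for fc2 and fc1 at 120 min, 46 and 70 for the fc2 and fc1 interactions at 30 min, and 108 for the fc1 interaction at 120 min. The array-spread covariate gave 6204 for the flu light response at 30 min, 1169 and 316 for flu and fc1 at 0 min, 4802 for flu at 30 min, 1042 for fc1 at 120 min, 351 for its interaction, and 3922 for fc2 against flu at 30 min. The larger side turned for the flu light response, for flu at 0 and 30 min and for fc2 against flu. Equal spread moved 0 of 25 counts, and the larger side turned for flu and fc1 at 0 min, fc2 at 120 min, the flu interaction at 30 min and the fc2 interaction at 120 min. Replicate numbers did not pair the arrays: over 66 pairs of groups the correlations of same-numbered deviations ran from -0.536 to 0.4 (median -0.008), and with the replicate block 0 of 25 counts moved, while of 244 named values AT3G49960 in fc2 at 0 min lost its call (adjusted p = 0.0696). Leaving out 1 array in turn, where the lone array is assumed to vary like other groups, gave these lowest and highest counts: light response of wt 837 to 1555, of fc2 382 to 436 and of fc1 1013 to 1117 at 30 min; against wt at 0 min, fc2 3 to 4, flu 180 to 378 and fc1 7 to 154; at 30 min, fc2 143 to 821, flu 5921 to 8747 and fc1 240 to 5417; at 120 min, fc2 2382 to 3408 and fc1 469 to 4373. Interactions at 30 min ran from 48 to 94 in fc2 and 22 to 67 in fc1, and at 120 min from 1255 to 2307 in fc2 and 110 to 241 in fc1. The other 10 contrasts stayed within 1.5 times. Of 225 list tests 114 were called, and 48 with an estimated correlation, and of 375 tests of added lists 81 and 17. Reference-gene scaling lost 5 and gained 2 of the 225 results, equal spread lost 5 and gained 8, the seed-gene covariate lost 4 and gained 3, the block gained 4 (light harvesting and photosystem and Calvin cycle in fc1 at 0 min, adjusted p = 0.0499 for both, photosystem and Calvin cycle in the fc1 interaction at 30 min, adjusted p = 0.0458, and singlet oxygen in the flu interaction at 120 min, adjusted p = 0.0468), and the mean of all probe sets per gene lost 1. The overlap of fc2 and flu calls at 120 min was 3266, and 497 at a change of at least 2-fold. No detection calls were used, so the signal over background of weak probe sets is unknown. An uncalled value in them sets no limit on a change.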

Other observations

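The 15 lists added after the annotation was seen were tests chosen after the design was fixed, and their members are named by smallest p, chosen after their values were seen. In flu at 120 min 18 of 20 thylakoid assembly genes were lower than in wt and 1 higher (18 and 1 adjusted over the list alone), with a mean of -2.39 ± 1.48 (adjusted p = 5.87e-15), led by CaS (-4.83 ± 0.12), the NDH subunit gene NdhN (-4.02 ± 0.12) and ATPC1, the gamma subunit of the chloroplast ATP synthase (-3.04 ± 0.1). Of 17 organelle RNA genes 9 were lower and 2 higher (9 and 2 adjusted over the list alone; list adjusted p = 0.0052), CRR42 with -3.29 ± 0.13 and CRR28 with -2.07 ± 0.13. With an estimated correlation the thylakoid assembly and organelle RNA lists both had adjusted p = 0.0421. Of 21 early immunity genes 13 were higher and 5 lower (13 and 5 adjusted over the list alone), GRX480 by 3.86 ± 0.19 and the U-box genes PUB24 and PUB23 by 2.27 ± 0.19 and 2.04 ± 0.18 (list adjusted p = 0.0286, and adjusted p = 0.127 with an estimated correlation). At 30 min 18 of 20 thylakoid assembly genes were already lower (19 adjusted over the list alone; list adjusted p = 6.3e-12, and adjusted p = 0.111 with an estimated correlation). The further auxin (mean 0.54, adjusted p = 0.00244), early immunity (0.4, 0.0285), further clock (-0.71, 0.0266) and redox (-0.25, 0.0266) lists were also called at 30 min, and none of them with an estimated correlation (adjusted p = 0.127, adjusted p = 0.127, adjusted p = 0.111 and adjusted p = 0.185 with an estimated correlation). Of the early immunity genes 11 were higher and 2 lower (11 and 2 adjusted over the list alone).

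In fc2 at 120 min 12 of 20 thylakoid assembly genes were lower than in wt (13 lower and 1 higher adjusted over the list alone), CaS with -1.38 ± 0.12 and NdhN with -1.3 ± 0.12 (list adjusted p = 6.84e-07, and adjusted p = 0.148 with an estimated correlation). Of 21 early immunity genes 9 were higher and 1 lower (10 and 2 adjusted over the list alone), GRX480 by 2.88 ± 0.19, WRKY22 by 1.63 ± 0.15 and UGT76B1 by 1.34 ± 0.11 (list adjusted p = 0.00261, and adjusted p = 0.0942 with an estimated correlation). Of 21 further folding genes 6 were higher and 1 lower (7 and 1 adjusted over the list alone; list adjusted p = 0.016, and adjusted p = 0.148 with an estimated correlation). In fc1 at 120 min 7 of 28 wall-loosening genes were lower and 1 higher (11 and 2 adjusted over the list alone), EXPB3 with -1.02 ± 0.16, EXPB1 with -0.89 ± 0.13 and XTH18 with 1.95 ± 0.18. The wall-loosening list had an adjusted p = 0.00224, and adjusted p = 0.137 with an estimated correlation. Of 19 sugar transport genes 3 were lower (5 adjusted over the list alone), SWEET4 with -1.02 ± 0.29 and SWEET3 with -1.0 ± 0.11 (list adjusted p = 0.00233, and adjusted p = 0.214 with an estimated correlation). At 0 min in fc2 the cold and dehydration list (mean -0.46, 1 of 13 lower and 3 adjusted over the list alone) and the further seed list (-1.01, 0 of 8 called and 0 adjusted over the list alone) were lower (adjusted p = 4.6e-05 and 0.0343, and adjusted p = 0.294 and adjusted p = 0.495 with an estimated correlation), where the seed-maturation means were 5.84 and 5.84 against 8.14 and 7.36 in wt.

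In wt the detoxification genes rose after 120 min, 12 of 22, with 1 lower (12 and 1 adjusted over the list alone; mean 0.66 ± 0.64, adjusted p = 3.39e-06), for example GSTU28 (1.69 ± 0.15) and AOR (1.43 ± 0.13). Of 21 further auxin genes 7 fell at 30 min (8 adjusted over the list alone; mean -0.46 ± 0.69, adjusted p = 4.18e-07), HAT2 with -1.17 ± 0.12 and LBD16 with -0.75 ± 0.09. In wt at 120 min the other added lists had means of -0.66 for further auxin (adjusted p = 0.0245, and adjusted p = 0.33 with an estimated correlation), 0.7 for cold and dehydration, 0.39 for sugar transport, 0.35 for redox, 0.26 for early immunity, 0.19 for further folding, 0.14 for further jasmonate, 0.1 for thylakoid assembly, 0.05 for reproductive, 0.02 for organelle RNA, -0.13 for wall loosening, -0.22 for further clock, -0.23 for cell division and -0.62 for further seed genes, and after further auxin none was called.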
